A study of Mus musculus with 64 samples.

How the data were processed

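Stool DNA from 64 mice was amplified with primers for the V4 region of the 16S rRNA gene, and paired reads were obtained on an Illumina MiSeq, per the labels. The deposited table held read counts per sequence feature and sample, with a Greengenes-style taxonomy for each feature. Its values were whole numbers with a smallest nonzero count of 2, and 71.5% of cells were 0. The denoising tool, the taxonomy release and any filtering by the authors are not given in the sources used here. The 64 columns matched the sample titles, and all libraries were kept, since none held fewer than 1000 reads.

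Samples were grouped by strain and genotype from the labels. Features were numbered within each taxon by total reads, because the table gives no short names, and counts were summed to 69 genera. A feature without a genus name was counted as an unclassified member of its lowest named rank, and 51.9% of reads carried a genus name. Genera and features were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust estimation and TMM factors, and Benjamini-Hochberg adjusted p-values were held against 0.05. Taxa were tested when found in at least 25% of the compared samples with at least 20 reads. DESeq2 1.42.0 with poscounts size factors and limma 3.58.1 on centred log-ratios of counts plus 0.5 served as other tools. Over the 4 strains, contrasts of the 8 group means tested the mean difference between knockouts and controls, its difference between strains, its difference between the Rorc and cMaf strains and the other strains, and differences among the 31 controls.

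Community tests were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Composition was compared by PERMANOVA on Bray-Curtis dissimilarity of feature shares. Richness was the expected number of features at 47133 reads, the depth of the shallowest library, and the Shannon index used the natural log of all reads. Differences in richness, Shannon index and lists were tested two-sided, and PERMANOVA for a larger share than under permuted labels, all by exact permutation except for 100000 random permutations in the Rorc strain and 9999 across strains. Lists of bacteria, including segmented filamentous bacteria, Helicobacteraceae, Verrucomicrobia, Bacteroides with Parabacteroides, Lachnospiraceae, S24-7, Lactobacillales, Actinobacteria and Deferribacteres, were compared as log2 of the summed percent plus 0.01. The community tests were adjusted over 16 tests, and the lists over those detected in a strain.

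The groups, tests, filters, lists, alternatives and the rule for naming taxa were chosen before the data were examined. The rule named, of genera past the threshold, the 10 with the largest fold change in each direction, and of features the 5 in each direction. Where fewer than 3 genera passed, it named the 5 with the smallest unadjusted p as not passing. It also named the 8 genera with the largest mean share, any list past its threshold, and 7 lists in any case. Over the 4 strains it named the 10 genera with the smallest adjusted p among those passing, or otherwise the 3 with the smallest unadjusted p. Features named outside this rule, such as feature 80 of unclassified Lachnospiraceae and Oscillospira feature 37, were chosen after their values were seen.

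Library sizes ran from 47133 to 89928 reads, so that a count of 0 allowed 3 reads, or up to 0.00636% in the shallowest library. Such limits cover counting error only, since amplified reads are not independent molecules. A fold against a group without reads was computed against a floor of 3 reads per library and is a lower bound. Litters, cages, sex and batches are not given for single mice, so p-values may measure only the spread between these samples. The community tests were tested on simulated data before use. The edgeR tests were tested after the fits of the real counts, on simulated counts with the means, depth and spread of those counts.

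Alternatives were library totals without TMM, the other tools, no filter, a filter of 50% of samples and 100 reads, no robust estimation, 1 spread for all 8 groups, the replicate number as a block, other dissimilarities, depths, pseudocounts of 0.1 and 0.001, and leaving out each mouse. Leaving out each mouse across strains, the controls' composition at equal depth or without abundant genera, and the fit of shared numbers without a block were added after the data were seen. No library and no column was left out of the main tests. The block and the fit of shared numbers without a block used only mice whose number occurred in both genotypes.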

Results

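Stool bacteria were profiled by sequencing the V4 region of the 16S rRNA gene from 64 mice, 33 of them knockouts and 31 controls. Each knockout lacked 1 transcription factor in Foxp3-expressing regulatory T cells, through a Foxp3-driven Cre recombinase acting on floxed alleles. The Rorc strain had 12 knockouts and 10 wild-type controls, the cMaf strain 5 and 6, the Helios strain 7 and 7, and the Gata3 strain 9 and 8. Rorc, which encodes RORγt, and cMaf act in the microbe-dependent subset of colonic regulatory T cells, whereas Helios and Gata3 mark the other main subset. Per the labels, controls were sex-matched littermates, mice were 6 to 8 weeks old, and the experimental batches spanned 3 years. The comparisons asked whether loss of these transcription factors in regulatory T cells altered the bacteria of the stool. Bacterial amplicons cannot show the deleted mouse gene, so the genotypes rest on the labels.

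The table held 854 sequence features, assigned to 69 genera or unclassified groups, with 4144352 reads. Libraries held 47133 to 89928 reads, with a mean of 64755.5 ± 8248.81 (SD, n = 64), and between 112 and 362 features were detected per mouse. A count of 0 allowed a share of up to 0.00334% in the deepest library and 0.00636% in the shallowest. Unclassified S24-7 (Muribaculaceae), a family of Bacteroidetes typical of the mouse gut, took 32.8% of reads on average. Allobaculum, of the Erysipelotrichaceae, took 14.2%, Lactobacillus, a genus of lactic acid bacteria, 13.7%, and Prevotella of the Prevotellaceae, degraders of plant polysaccharides, 9.62%. Unclassified Clostridiales (6.11%), unclassified Lachnospiraceae (5.43%), Prevotella of the Paraprevotellaceae (2.57%) and Bacteroides (2.11%) completed the 8 most abundant groups, which together held 86.6% of reads.

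In the Rorc strain the abundant bacteria of knockouts and controls differed by less than the spread between mice. Unclassified S24-7 held 25.4% ± 10.2 of reads in knockouts (SD, n = 12) and 33.6% ± 14.9 in controls (SD, n = 10). Lactobacillus held 21.1% ± 17.2 and 20.2% ± 17.1, Allobaculum 11.5% ± 19.4 and 12.7% ± 16.0, and Prevotella of the Prevotellaceae 12.6% ± 9.04 and 9.75% ± 8.49. Unclassified Clostridiales stood at 5.16% ± 4.23 and 4.22% ± 2.20, unclassified Lachnospiraceae at 6.16% ± 5.24 and 4.22% ± 2.83, Prevotella of the Paraprevotellaceae at 4.01% ± 3.35 and 2.12% ± 2.22, and Bacteroides at 1.76% ± 0.983 and 2.37% ± 1.98. Segmented filamentous bacteria, which attach to the ileal epithelium and induce Th17 cells, were found in 10 of 12 knockouts and 8 of 10 controls, at 0.110% ± 0.104 and 0.0629% ± 0.0702.

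With edgeR, 0 of 47 genera in the Rorc strain passed the adjusted threshold, and 0 had an unadjusted p under 0.05. DESeq2 and limma also called 0 genera, with 0 and 1 at that unadjusted level. The 5 genera with the smallest unadjusted p, none of which passed, all had an adjusted p of 0.950. They were Butyricicoccus, a butyrate producer (log2 fold change of knockout over control -1.80 ± 1.03, SE), Chlamydia, an obligate intracellular genus (2.82 ± 1.69), Helicobacter (-0.80 ± 0.54), unclassified Peptococcaceae (-1.44 ± 1.03) and Dehalobacterium (-1.15 ± 0.86). Chlamydia was found in 6 of 12 knockouts and 5 of 10 controls. Of its 2383 reads over all mice of the study, 348 remained without Rorc knockout 7. Of 318 features, 0 passed with edgeR and 4 had an unadjusted p under 0.05, against 0 and 3 with DESeq2 and 0 and 10 with limma. Of the 24 bacterial lists detected, 0 passed and 0 had an unadjusted p under 0.05. Actinobacteria had the smallest p, at 0.904% ± 0.746 in knockouts and 1.56% ± 1.01 in controls (permutation p = 0.0797, adjusted p = 0.896). Among the other lists, Lachnospiraceae held 8.04% ± 7.05 and 5.53% ± 3.39, Lactobacillales 21.2% ± 17.2 and 20.2% ± 17.1, Bacteroides with Parabacteroides 2.27% ± 1.28 and 2.77% ± 2.36, Helicobacteraceae 0.762% ± 0.4931 and 1.05% ± 0.918, and Verrucomicrobia 0.0120% ± 0.0283 and 0.105% ± 0.312. Adjusted over the list alone, 0 features passed in the 19 lists with tested features. Genotype accounted for 3.22% of the variation in Bray-Curtis dissimilarity, against a mean of 4.78% under permuted genotypes (permutation p = 0.727). Richness was 231 ± 71.1 and 233 ± 53.8 features (permutation p = 0.927), and the Shannon index 3.63 ± 0.634 and 3.68 ± 0.431 (permutation p = 0.811).

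The cMaf strain also showed wide overlap between knockouts and controls. Unclassified S24-7 held 35.1% ± 12.1 of reads in knockouts (SD, n = 5) and 32.8% ± 13.1 in controls (SD, n = 6). Allobaculum stood at 12.4% ± 15.2 and 13.1% ± 9.90, unclassified Clostridiales at 8.57% ± 4.03 and 12.7% ± 6.83, Prevotella of the Prevotellaceae at 9.86% ± 3.22 and 7.85% ± 5.19, and unclassified Lachnospiraceae at 7.03% ± 3.23 and 9.29% ± 4.73. Lactobacillus held 5.08% ± 3.26 and 2.51% ± 2.64, and Bacteroides, a genus of polysaccharide degraders, 3.39% ± 5.24 and 1.34% ± 2.02. Segmented filamentous bacteria were found in 3 of 5 knockouts and 4 of 6 controls, at 0.0131% ± 0.0180 and 0.0242% ± 0.0269.

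Of 48 genera in the cMaf strain, edgeR, DESeq2 and limma each called 0, and each gave 0 with an unadjusted p under 0.05. Bifidobacterium had the smallest unadjusted p and did not pass, at 0.0591% ± 0.0469 and 0.450% ± 0.884 (log2 -3.20 ± 1.71, SE, adjusted p = 0.974). It was followed by Christensenella (-2.14 ± 1.40), Ruminococcus of the Ruminococcaceae (-0.72 ± 0.48), Prevotella of the Paraprevotellaceae (2.52 ± 1.80, with 0.918% ± 0.945 and 0.255% ± 0.211 of reads) and Flexispira (-3.05 ± 2.28), with the same adjusted p. Of 408 features, 0 passed with edgeR and 15 had an unadjusted p under 0.05, against 0 and 10 with DESeq2 and 0 and 6 with limma. The smallest p belonged to an unclassified Lachnospiraceae feature, numbered 80 here, found in 0 of 5 knockouts and 4 of 6 controls, at least 14.9-fold lower in knockouts (adjusted p = 0.627). Deferribacteres had the smallest p of 22 lists, 0 of which passed or had an unadjusted p under 0.05, at 0.162% ± 0.249 and 0.390% ± 0.401 (exact permutation p = 0.134, adjusted p = 0.929). Helicobacteraceae held 4.39% ± 5.94 and 3.60% ± 3.89, Lachnospiraceae 9.33% ± 4.39 and 12.03% ± 6.10, Lactobacillales 5.11% ± 3.25 and 2.53% ± 2.66, Bacteroides with Parabacteroides 3.88% ± 5.39 and 1.68% ± 1.99, and Verrucomicrobia 0.0108% ± 0.0165 and 0.0236% ± 0.0383. On the log scale of the test Helicobacteraceae had the opposite sign to its means, at -0.31. Adjusted over the list alone, 0 features passed in 21 lists. Genotype accounted for 5.80% of the variation, against 10% under permuted genotypes (exact permutation p = 0.734). Richness was 268 ± 56.8 and 306 ± 81.6 (exact permutation p = 0.379), and the Shannon index 4.10 ± 0.425 and 4.37 ± 0.511 (exact permutation p = 0.379).

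Helios knockouts carried the same dominant groups as their controls. Unclassified S24-7 held 30.1% ± 13.8 of reads in knockouts (SD, n = 7) and 32.996% ± 9.68 in controls (SD, n = 7), Allobaculum 12.8% ± 11.7 and 14.4% ± 12.9, and Prevotella of the Prevotellaceae 11.1% ± 4.81 and 9.16% ± 7.46. Lactobacillus stood at 6.85% ± 4.08 and 12.7% ± 10.4, unclassified Clostridiales at 9.72% ± 6.39 and 6.52% ± 6.11, unclassified Lachnospiraceae at 7.27% ± 6.44 and 5.54% ± 3.17, Prevotella of the Paraprevotellaceae at 5.02% ± 4.48 and 2.95% ± 3.12, and Bacteroides at 1.94% ± 1.34 and 1.94% ± 1.93. Segmented filamentous bacteria were found in 5 of 7 knockouts and 5 of 7 controls, at 0.0663% ± 0.0952 and 0.0396% ± 0.0779.

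Adlercreutzia, a genus of equol-producing Actinobacteria, had the smallest unadjusted p in the Helios strain and did not pass. It held 0.0312% ± 0.0236 in knockouts and 0.0670% ± 0.0377 in controls (log2 -1.46 ± 0.62, SE, adjusted p = 0.992). The next 4 genera did not pass either. They were unclassified Rickettsiales (2.82 ± 1.60), Lactobacillus (-1.12 ± 0.67), Turicibacter (-4.03 ± 2.81, found in 1 of 7 knockouts and 3 of 7 controls) and Desulfovibrio, a sulfate reducer (-1.0005 ± 0.71). Of 47 genera, edgeR, DESeq2 and limma each called 0 and each gave 1 with an unadjusted p under 0.05. Of 358 features, 0 passed with edgeR and 1 had an unadjusted p under 0.05, against 0 and 2 with DESeq2 and 0 and 4 with limma. Among 22 lists, 0 passed and 0 had an unadjusted p under 0.05. Actinobacteria had the smallest, at 0.402% ± 0.379 and 0.613% ± 0.345 (exact permutation p = 0.121, adjusted p = 0.895). Lactobacillales held 6.89% ± 4.10 and 12.8% ± 10.4, Lachnospiraceae 9.54% ± 8.31 and 7.87% ± 4.36, Bacteroides with Parabacteroides 2.47% ± 1.57 and 2.42% ± 2.17, and Helicobacteraceae 1.34% ± 0.986 and 1.001% ± 0.869. Verrucomicrobia were found in 1 of 7 knockouts and 0 of 7 controls. Adjusted over the list alone, 0 features passed in 19 lists. Genotype accounted for 4.84% of the variation, against 7.69% under permuted genotypes (exact permutation p = 0.7995). Richness was 277 ± 47.2 and 261 ± 37.4 (exact permutation p = 0.471), and the Shannon index 4.10 ± 0.387 and 3.96 ± 0.330 (exact permutation p = 0.473).

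In the Gata3 strain, Lactobacillus held 9.59% ± 8.25 of reads in knockouts (SD, n = 9) and 20.1% ± 13.7 in controls (SD, n = 8), and Allobaculum 22.3% ± 18.5 and 14.2% ± 13.6. Neither genus passed the test. Unclassified S24-7 held 37.9% ± 11.8 and 38.0% ± 9.24, Prevotella of the Prevotellaceae 9.05% ± 10.2 and 5.89% ± 2.52, and unclassified Clostridiales 3.20% ± 2.60 and 3.20% ± 3.57. Unclassified Lachnospiraceae stood at 2.74% ± 3.06 and 3.25% ± 3.63, Prevotella of the Paraprevotellaceae at 1.92% ± 2.53 and 2.03% ± 2.33, and Bacteroides at 2.41% ± 1.28 and 2.08% ± 1.39. Verrucomicrobia, here mainly the mucin degrader Akkermansia, were found in 4 of 9 knockouts and 3 of 8 controls, at 1.71% ± 3.44 and 1.65% ± 3.16. Segmented filamentous bacteria were found in 6 of 9 knockouts and 2 of 8 controls, at 0.0274% ± 0.0373 and 0.0168% ± 0.0312.

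The 5 genera with the smallest unadjusted p in the Gata3 strain, none past the threshold, shared an adjusted p of 0.959. They were unclassified RF39, an uncultured group of Mollicutes (2.95 ± 1.33, log2 with SE), unclassified Coriobacteriaceae (1.40 ± 0.65), Coprococcus (1.37 ± 0.71), Mucispirillum, a resident of the mucus layer (-1.78 ± 1.02), and unclassified RF32, an uncultured group of Alphaproteobacteria (1.99 ± 1.35). Of 48 genera, edgeR called 0 with 2 at an unadjusted p under 0.05, DESeq2 0 with 3, and limma 0 with 0. Of 282 features, edgeR called 0 with 5 at that level, DESeq2 1 with 5, and limma 0 with 12. The DESeq2 call was an Oscillospira feature, numbered 37 here, found in 5 of 9 knockouts and 0 of 8 controls, at least 12.9-fold higher in knockouts (DESeq2 adjusted p = 0.0386, edgeR adjusted p = 0.148). Adjusted over the list alone, 2 features passed in the 21 lists with tested features, against 0 over all features. These were Oscillospira feature 37 in the Ruminococcaceae group (adjusted p = 0.0339) and Allobaculum feature 2 in the Erysipelotrichia (adjusted p = 0.0444, and 0.348 over all features). Allobaculum feature 2 held 0.00922% ± 0.0196 and 4.58% ± 6.57, and was found in 3 of 9 knockouts and 3 of 8 controls. Of 25 lists, 0 passed and 0 had an unadjusted p under 0.05. Lactobacillales had the smallest, at 9.65% ± 8.25 and 20.2% ± 13.7 (exact permutation p = 0.206, adjusted p = 1). Lachnospiraceae held 4.26% ± 4.02 and 4.70% ± 4.97, Bacteroides with Parabacteroides 3.02% ± 1.27 and 2.60% ± 1.65, and Helicobacteraceae 0.510% ± 0.615 and 0.809% ± 1.02. Genotype accounted for 8.70% of the variation, against 6.25% under permuted genotypes (exact permutation p = 0.162). Richness was 212 ± 37.7 and 206 ± 62.3 (exact permutation p = 0.791), and the Shannon index 3.45 ± 0.421 and 3.61 ± 0.435 (exact permutation p = 0.444).

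**Figure D1:**
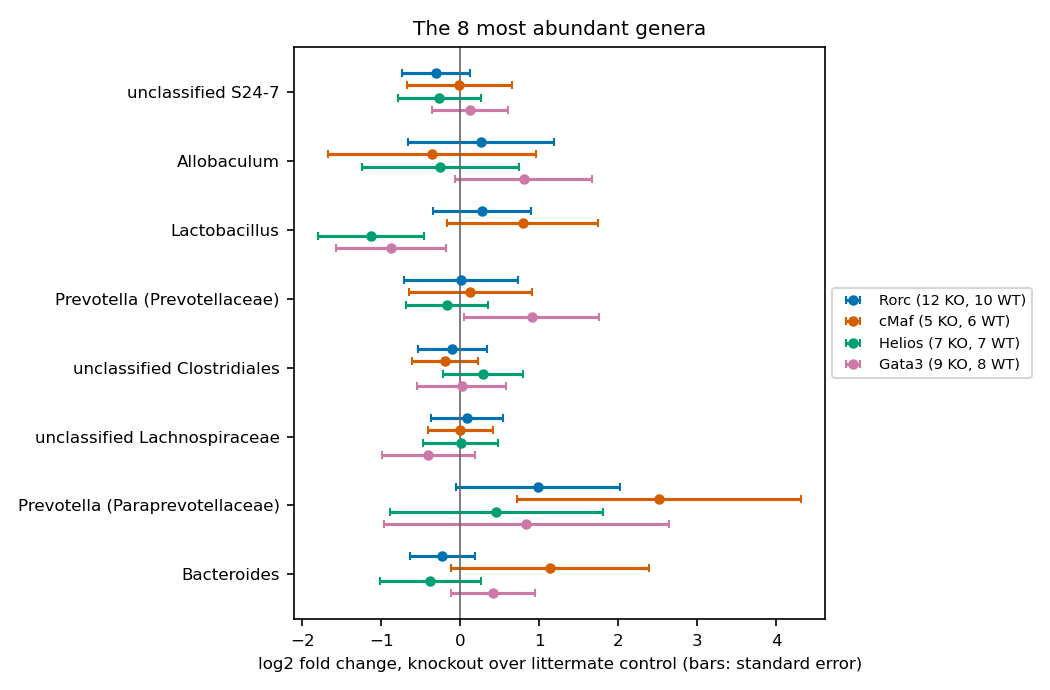
The log2 fold change of knockouts over controls is plotted for each of the 8 most abundant genera in the 4 strains, with points for the edgeR estimate and bars for its standard error. None of these estimates passed the adjusted threshold, and the largest, 2.52 ± 1.80 for Prevotella of the Paraprevotellaceae in the cMaf strain, had an adjusted p of 0.974.

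**Figure D2:**
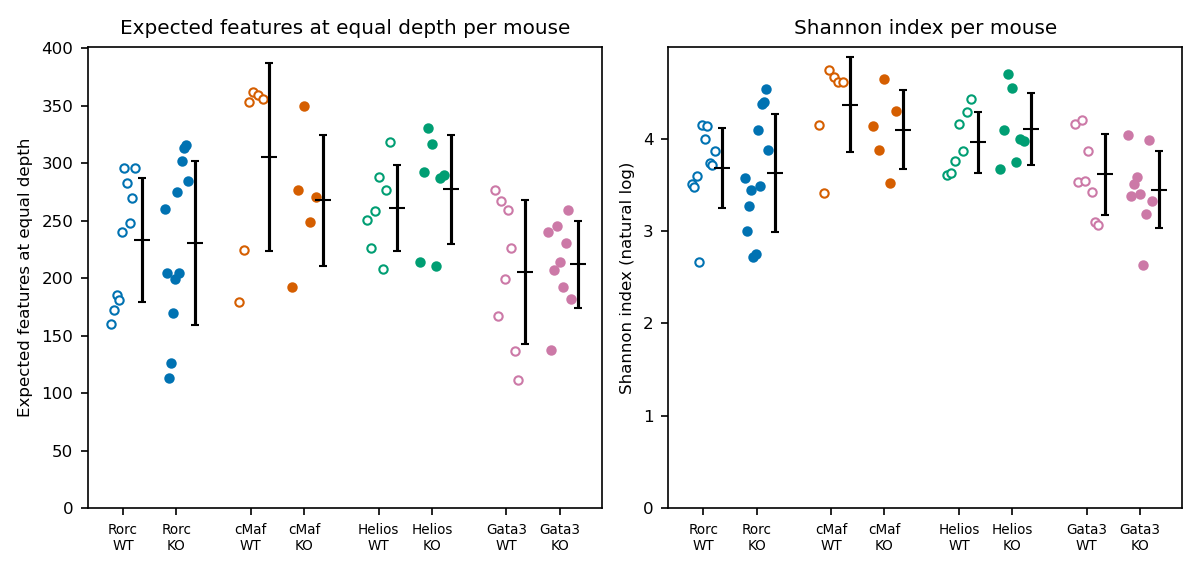
Richness (left, expected features at 47133 reads) and the Shannon index (right, natural log) are plotted for each mouse, with open points for controls, filled points for knockouts, and bars for the mean and SD. Knockouts and controls overlapped in each strain, with Gata3 richness at 212 ± 37.7 in knockouts and 206 ± 62.3 in controls.

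The size of change that could be detected within a strain was limited. In simulated data with the depth and spread of these libraries, edgeR recovered 7 to 16% of genera changed 4-fold and 55 to 83% of those changed 16-fold. Those values come from 10 runs with 10 genera changed. For features, in 1 run per strain and fold with 141 to 200 features changed, recovery was 0.709 to 5.03% at 4-fold and 5.5% (cMaf) to 62.3% (Rorc) at 16-fold, so the values for genera and features are not directly comparable. In simulated communities with 200 of 854 features changed 4-fold, the composition test called 24 of 40 runs with 5 against 6 libraries. With 7 against 7 libraries it called 32 of 40. At 16-fold it called 40 of 40 for either size, and without a change 2 and 5 of 40. The spread in these communities was not taken from the libraries, so the counts do not give the power of the real tests. Over the 16 tests of composition, dispersion, richness and Shannon index, adjusted p was 0.865 or more. Among the 8 most abundant genera, the fitted fold and the difference in mean shares had opposite signs for Allobaculum and unclassified Clostridiales in the Rorc strain, unclassified S24-7 and unclassified Lachnospiraceae in the cMaf strain, Prevotella of the Prevotellaceae and Bacteroides in the Helios strain, and unclassified S24-7, unclassified Clostridiales and Prevotella of the Paraprevotellaceae in the Gata3 strain.

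Over the 4 strains together, unclassified RF32 was the genus that rose in knockouts, by a log2 fold change of 3.14 ± 0.82 (SE, edgeR adjusted p = 0.0183), a fitted value that depends on the prior count because 2 control groups were all at 0. RF32 was found in 2 of 12 Rorc, 3 of 5 cMaf, 2 of 7 Helios and 5 of 9 Gata3 knockouts, and in 0 of 10, 5 of 6, 0 of 7 and 3 of 8 controls. Among the knockout groups its mean share ranged from 0.00333% ± 0.00912 in Rorc (SD, n = 12) to 0.0778% ± 0.121 in cMaf (SD, n = 5). Among controls it was 0.0271% ± 0.0157 in cMaf and 0.00548% ± 0.00911 in Gata3, with no reads in Rorc and Helios. The call ended without Helios knockout 6 (log2 2.62 ± 0.79, adjusted p = 0.0881) or Rorc knockout 3 (2.62 ± 0.76, adjusted p = 0.0594), and with DESeq2 (2.91 ± 1.10, adjusted p = 0.199). Of 49 genera, edgeR called 1 and 2 had an unadjusted p under 0.05, while DESeq2 called 0 with 2. None of the 8 most abundant genera passed, with Lactobacillus at -0.35 ± 0.39, unclassified S24-7 at -0.21 ± 0.31 and Prevotella of the Paraprevotellaceae at 1.201 ± 0.84 (log2 with SE). Genotype within strains accounted for 1.70% of the variation in Bray-Curtis dissimilarity (permutation p = 0.193).

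The difference between knockouts and controls was then compared between strains. With edgeR, 0 of 49 genera passed and 2 had an unadjusted p under 0.05, against 0 and 1 with DESeq2. Unclassified Peptococcaceae (adjusted p = 0.420), Akkermansia (adjusted p = 0.828) and Clostridium of the Clostridiaceae (adjusted p = 0.899) had the smallest unadjusted p and did not pass. For the Rorc and cMaf strains against the Helios and Gata3 strains, edgeR called 0 with 5 at an unadjusted p under 0.05, and DESeq2 0 with 3. Here unclassified Peptococcaceae stood at -4.02 ± 1.24 (log2 with SE, adjusted p = 0.0967), Lactobacillus at 1.87 ± 0.79 (adjusted p = 0.456) and Clostridium of the Clostridiaceae at 2.75 ± 1.27 (adjusted p = 0.456). Unclassified Peptococcaceae had reads in 2 of 17 Gata3 mice, none of them controls. Clostridium of the Clostridiaceae had reads in 2 of 11 cMaf mice, none of them controls. The fitted values of these genera therefore depend on the prior count. Lactobacillus held 21.1% and 20.2% of reads in Rorc knockouts and controls, 5.08% and 2.51% in cMaf, 6.85% and 12.7% in Helios, and 9.59% and 20.1% in Gata3.

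Wild-type controls differed between the 4 strains. Lactobacillus held 20.2% ± 17.1 of reads in Rorc controls (SD, n = 10), 2.51% ± 2.64 in cMaf (SD, n = 6), 12.7% ± 10.4 in Helios (SD, n = 7) and 20.1% ± 13.7 in Gata3 controls (SD, n = 8). Ruminococcus of the Ruminococcaceae, a family of fibre fermenters, held 0.520% ± 0.330, 2.18% ± 1.26, 0.776% ± 0.518 and 0.474% ± 0.409 in the same order. AF12, of the Rikenellaceae, was found in 6 of 10 Rorc, 0 of 6 cMaf, 7 of 7 Helios and 5 of 8 Gata3 controls, and Rikenella in 3, 5, 0 and 0. Akkermansia was found in 1 of 10, 4 of 6, 0 of 7 and 3 of 8 controls, at up to 8.21% of reads in the Gata3 strain.

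These genera, with unclassified RF32, unclassified Peptococcaceae, Clostridium of the Clostridiaceae and Coprobacillus, were the 9 of 49 that changed between control groups (edgeR adjusted p from 0.0117 for RF32 to 0.0474 for Lactobacillus). With edgeR 13 genera had an unadjusted p under 0.05, and DESeq2 called 11 with 16 at that level. RF32 was found in 5 of 6 cMaf and 3 of 8 Gata3 controls, and unclassified Peptococcaceae in 8 of 10 Rorc, 6 of 6 cMaf, 3 of 7 Helios and 0 of 8 Gata3 controls. Clostridium of the Clostridiaceae was found in 6, 0, 4 and 7 controls in that order, and Coprobacillus in 7, 0, 3 and 4. The count rested on single cMaf controls: it was 0 without cMaf control 5 (smallest adjusted p = 0.0513), 1 without control 3, 3 without control 4 and 5 without control 2, and it was 5 without Rorc control 9. Strain accounted for 20.9% of the variation in Bray-Curtis dissimilarity among controls, against 9.99% under permuted strains, and for 26.3% among knockouts (permutation p = 0.0001 for both, the smallest that the permutations can give). The permutations treated mice as independent, whereas mice with adjacent numbers in a group lay at a mean dissimilarity of 0.503 and others at 0.630. On genera instead of features, strain accounted for 17.3% among controls (permutation p = 0.0352) and 16.7% among knockouts (permutation p = 0.0316).

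**Figure D3:**
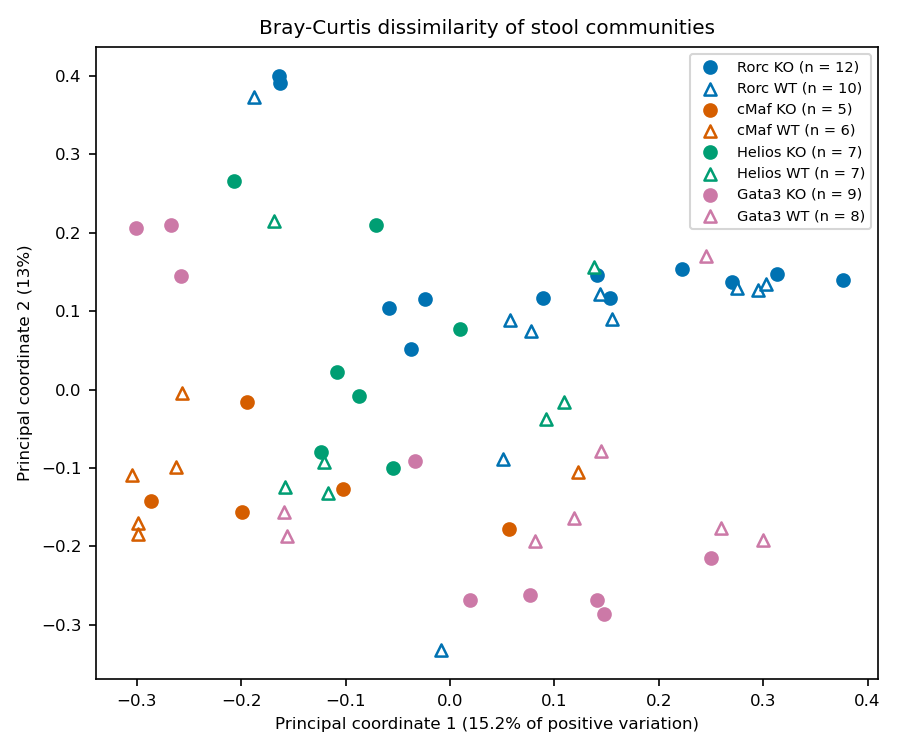
Each point is 1 mouse on the first principal coordinates of Bray-Curtis dissimilarity, with 15.2% and 13% of the positive variation on the axes, coloured by strain, filled for knockouts and open for controls. Strains occupied partly separate areas, and genotype within strains accounted for 1.70% of the variation.

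**Figure D4:**
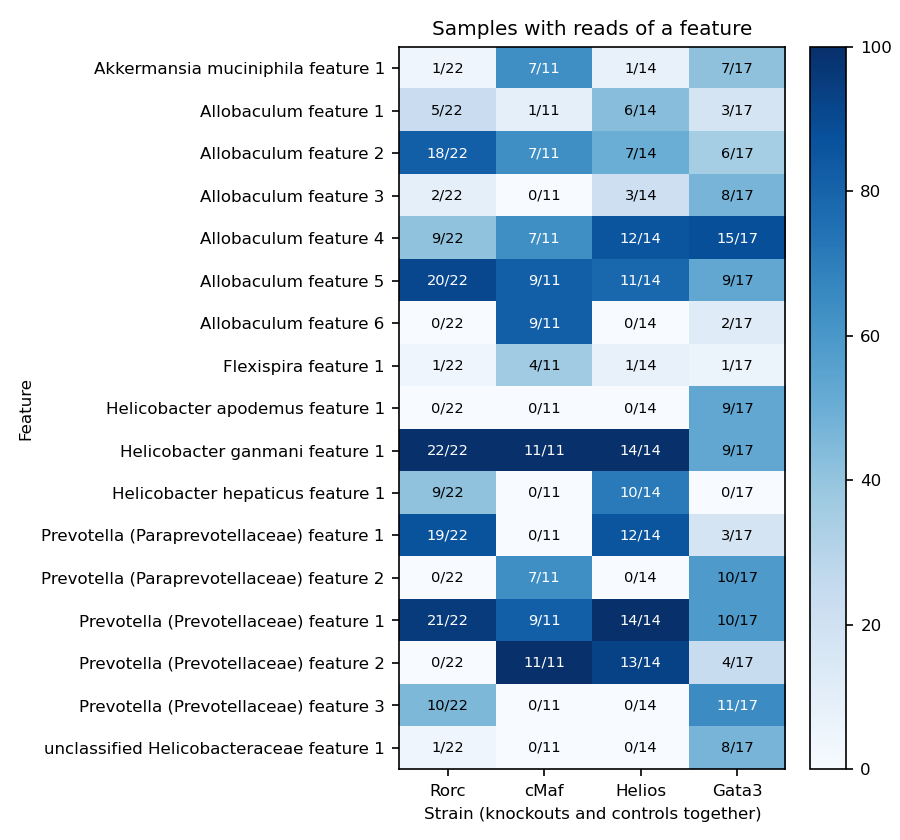
Shading and numbers give the mice with reads of each feature, knockouts and controls together, out of the mice of each strain, for features of Akkermansia, Allobaculum, the Helicobacteraceae and Prevotella. Prevotella (Prevotellaceae) feature 2 was found in 0 of 22 Rorc and 11 of 11 cMaf mice, and Helicobacter hepaticus in 0 of 11 cMaf and 0 of 17 Gata3 mice.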

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

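The tests of other splits, of RF32 (single mice and shared effect), of depth, abundant genera and colony features among controls, and of nearest and neighbouring mice were chosen only after the result was seen.

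Single mice stood apart from their group in 11 of 125 comparisons of a group on 1 measure, where chance gives about 1 in 20, with shares compared on a log2 scale. The comparisons covered 18 measures in 7 of the 8 groups. Some measures overlap, such as Lactobacillales and Lactobacillus, and some shares were 0, so the rate given by chance is only a guide. Rorc control 3 had a Shannon index of 2.67, below its group's next value of 3.47. Rorc control 10 held 0.992% Verrucomicrobia, against 0.0590% in the next mouse, and 0% Prevotella of the Prevotellaceae, against 2.25%. Gata3 control 8 also held 0% of that Prevotella, against 4.82%. Helios control 4 held 0.214% segmented filamentous bacteria, against 0.0281%, and Helios knockout 4 held 0.00298% Verrucomicrobia, against 0. This last value is under the limit that a count of 0 allows, in a group otherwise at 0 where any read would stand apart. Helios knockout 5 held 0.540% Lactobacillales and 0.508% Lactobacillus, against 4.10% and 4.08%. Helios knockout 3 and Helios control 3 held 0% Prevotella of the Paraprevotellaceae, against 0.560% and 1.24%. In cMaf control 6, Allobaculum held 0.655%, against 8.83%.

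Unclassified RF32 rose in knockouts over the 4 strains, by 3.14 ± 0.82 on the log2 scale. Leaving out either of 2 of the 64 mice ended the call, the outcome set before its value was seen as the mark of dependence on a single mouse. The fold was 2.62 ± 0.79 (SE) without Helios knockout 6 and 2.62 ± 0.76 without Rorc knockout 3. These errors do not measure the shift between fits that share mice. Dependence on a single mouse was called open only after these values were seen. An effect shared by the 4 knockouts also remained open: RF32 was more frequent in knockouts in 3 of 4 strains, with no difference past 0.05 by Fisher's exact test (p = 0.481 in Rorc, 0.462 in Helios and 0.637 in Gata3), while in cMaf it was found in 3 of 5 knockouts and 5 of 6 controls (Fisher's exact p = 0.545) and its mean share was 0.0778% ± 0.121 in knockouts and 0.0271% ± 0.0157 in controls. Chance could not be excluded: 39 of 100 splits within strains gave at least the real count of 1 genus, and the highest other split gave 4. Batch remained untested.

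Control mice differed between strains in composition, with 20.9% of the variation. A difference in depth is argued against, since strain took 20.9% with every library thinned to equal depth (permutation p = 0.0001), and so is dominance by a few taxa, since it took 21.8% without the 8 most abundant genera (permutation p = 0.0001), in both cases the smallest p possible. For the 9 genera called, 1 of 100 splits, the real one, gave as many and the highest other gave 2, which excludes chance only if mice are independent, and mice with adjacent numbers were more alike; the count was 0 without cMaf control 5. A candidate explanation is a stable set of bacteria in each colony: for 131 of 459 features whose presence differed between control groups, differences in frequency from the mean correlated with those in knockouts at r = 0.865, across features that are not independent, against 0.690 at most in permuted data. The knockouts are not independent of the controls, their littermates per the labels, and shared litters, cages or batches could also give this correlation. Colony, batch, age within the range and housing are not labelled apart from strain and remained open.

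Mice of a strain resembled those of the other genotype about as closely as those of their own. Mean Bray-Curtis dissimilarity was 0.597 over 271 pairs of other genotype and 0.601 over 242 pairs of the same genotype, knockouts and controls pooled. Pairs of knockouts lay at 0.583 in Rorc, 0.641 in cMaf, 0.557 in Helios and 0.614 in Gata3. Pairs of a knockout and a control lay at 0.586, 0.574, 0.552 and 0.656 in that order. Housing or litter shared across genotypes remained open: the nearest mouse of the strain had the other genotype for 30 of 64 mice, where 33.9 were expected from permuted genotypes, which the absence of a genotype effect gives with or without shared housing. Collection of mice with neighbouring numbers together remained open. Adjacent numbers within a group lay at 0.503 over 56 pairs and others at 0.630 over 186 pairs (permutation p = 0.0001, the smallest possible), and closer in 8 of 8 groups. The mice of these pairs share a genotype, so the test cannot show whether collection made knockouts resemble controls. A biological effect of genotype on composition smaller than the tests could detect remained open.

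Within strains edgeR called 0 genera and 0 features, so that 100 of the 100 splits gave at least as many by construction, and the splits say nothing about chance in these 8 comparisons. The highest other splits gave 2 genera and 3 features in Rorc, 3 and 14 in cMaf, 1 and 4 in Helios, and 1 and 7 in Gata3. Both contrasts of the knockout effect between strains also had 0 genera in the real split, and 4 in the highest other split of each.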

How the results depend on the processing

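Of 798 settings of 30 results, 766 were held the same and 32 were not. A count of taxa was held the same when equal or, if above 0, of similar size. Any other result had to keep its side of the threshold and, for a signed difference, its direction. Of 4402 settings of 124 named taxa and lists, 4365 kept their call or lack of a call, or had no adjusted p. Among the others, 3 gained and 34 lost a call, and 0 turned after a call. The 4365 include 292 settings that changed the sign of an uncalled value, in 51 taxa or lists. DESeq2 gave no adjusted p for Akkermansia across strains or among controls. Leaving out each mouse across strains was added after the data were seen.

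Without a filter, 102 features passed in the Rorc strain (46 higher, 56 lower) and 23 in the Gata3 strain (10 and 13). Of the 102, 63 had reads in 1 mouse and the most widespread in 7 of 22, and of the 23 the most widespread had reads in 5 of 17. With DESeq2, 1 Gata3 feature passed. For the 4 strains together, 0 genera passed with DESeq2, 0 under the stricter filter, which did not test RF32, and 2 without a filter (RF32 and Defluviitalea). Leaving out 1 mouse gave 0 to 2. The contrast of the Rorc and cMaf strains with the Helios and Gata3 strains gave 1 genus without a filter, Flexispira, found in 7 mice. Among controls 17 genera passed without a filter, 5 under the stricter one, and 0 to 10 with 1 mouse left out. The knockout-minus-control difference in Rorc richness, -2.48, ran from -10.6 to 8.21 with 1 mouse left out, and Gata3 richness, 6.57, from -6.80 to 16.7. The Rorc difference in Shannon index ran from -0.170 to 0.0260 with 1 mouse left out, and was 1.08 for the inverse Simpson index. These differences passed no threshold in any setting, and the cause of their changes of sign was not tested.

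Replicate numbers were not taken to pair the mice, since not every pair correlated over 0.1, though a partial pairing is not excluded: same-numbered mice correlated over 0.1 in 6 of 10 Rorc, 3 of 5 cMaf, 4 of 7 Helios and 5 of 8 Gata3 pairs, and both members correlated best with their own number in 0, 1, 2 and 3, with median correlations of 0.118, 0.216, 0.176 and 0.221. For each number, the mean correlation with mice of other numbers lay between -0.262 and 0.0646. With the number as a block, 0 genera and 0 features passed in any strain. The block kept only mice whose number both genotypes held, which left out Rorc knockouts 11 and 12, cMaf control 6 and Gata3 knockout 9. Over the kept mice the Rorc richness difference was 19.7, against -2.48 over all, because mice were left out. Genotype took a fraction of 0.0995 of variation over the kept Gata3 mice, with p = 0.0469 by permutation within numbers. By free permutation with any 1 Gata3 mouse left out, p was 0.109 or more. Depth limited taxa below 0.00636% in the shallowest library.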

Other observations

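The tests of Helicobacter, Chlamydia and the label of Rorc control 10 were chosen only after the pattern was seen, and of these the bound for a swap was set before its value was seen.

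Features labelled as Helicobacter species differed between the strains. Each species name rests on 1 feature and on the deposited taxonomy, and was not checked. Helicobacter hepaticus, a colonic species known to induce RORγt-expressing regulatory T cells, was found in 9 of 22 Rorc mice and 10 of 14 Helios mice, and in 0 of 11 cMaf and 0 of 17 Gata3 mice. Helicobacter ganmani was found in 22 of 22 Rorc, 11 of 11 cMaf, 14 of 14 Helios and 9 of 17 Gata3 mice, at 3.95% ± 4.68 of reads in cMaf (SD, n = 11) and 0.369% ± 0.698 in Gata3 (SD, n = 17). Helicobacter apodemus was found in 9 of 17 Gata3 mice and in 0 mice of the other strains. A pair of S24-7 features, numbered 59 and 79 here, was found in 11 of 11 cMaf mice and in 0 of the other mice. Prevotella (Prevotellaceae) feature 2 was found in 0 of 22 Rorc and 11 of 11 cMaf mice. Of 41 genera examined, presence differed between strains for 17 after adjustment and 19 before, over knockouts and controls together, among them AF12, found in 0 of 11 cMaf and 14 of 14 Helios mice, and Mycoplasma, found in 4 of 11 cMaf mice and 0 of the others. These taxa were chosen after their values were seen. The presence test treated mice as independent, whereas mice with adjacent numbers in a group were more alike.

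Features of Allobaculum differed in how many mice carried them. Feature 5 was found in 49 of 64 mice and feature 4 in 43. Allobaculum feature 1 was found in 15 mice and reached 50.2% of reads in Rorc control 3, while Allobaculum feature 6 was found in 9 of 11 cMaf mice, 2 of 17 Gata3 mice and 0 of 22 Rorc mice.

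Mice of the Gata3 strain might carry either Helicobacter ganmani or the other Helicobacteraceae features. This remained open: 6 mice held both, 3 held Helicobacter ganmani alone, 8 held the others alone and 0 held neither (2-sided Fisher's exact p = 0.206). With 9 and 14 of 17 mice positive, 6 is the fewest that could hold both, so that the test could not pass in this direction.

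Whether carriage of Chlamydia follows the colony and not the knockout remained open. Its presence by strain (permutation p = 0.0005, adjusted p = 0.00228 over 41 genera) is the pattern that prompted the test and does not support it independently. It was found in 11 of 22 Rorc, 0 of 11 cMaf, 1 of 14 Helios and 1 of 17 Gata3 mice, and in 6 of 12 Rorc knockouts and 5 of 10 Rorc controls (Fisher's exact p = 1, with a 95% interval of the odds ratio from 0.139 to 7.21). Rorc knockout 7 held 3.48%, and the next mouse, Gata3 control 4, 0.114%.

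Rorc control 10 lay nearest to Gata3 control 8, at a Bray-Curtis dissimilarity of 0.218. That it is a Gata3 mouse labelled as Rorc cannot be told apart from a true Rorc mouse: its mean dissimilarity to Gata3 mice exceeded that to the other Rorc mice by 0.0315, within the SD of 0.154 of its values to Gata3 mice. A swap of a Rorc and a Gata3 mouse could also not be told apart, since 3 Gata3 samples lay closer on average to Rorc mice than to the other Gata3 mice, but 10 of all 64 mice lay closer to another strain. Rorc control 10 was not among these 10. Rorc control 4 was, at a mean of 0.612 to Gata3 mice and 0.761 to Rorc mice, and its 5 nearest mice were all Gata3. Gata3 controls 4 and 8 lay at means of 0.529 and 0.732 to Rorc mice, against 0.688 and 0.796 to Gata3 mice. The labels of these 3 controls were not tested.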
